A study of Mus musculus with 16 samples.

How the data were processed

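Total hepatic RNA in 16 samples from mice of the C57BL/6 background was labelled with biotin and hybridised to Affymetrix Mouse Gene 1.0 ST arrays, per the labels' protocols. These arrays carry probes along the length of each transcript and report 1 value per transcript cluster, called a row here. The sample titles give the groups, 7 Pdgf-c transgenic and 9 wildtype arrays, and number the replicates within each group. The source and cell type labels read stromal cells, whereas the protocol describes RNA of the whole liver, and the samples are treated here as whole liver. The deposited values were used as log2 intensities: per the submitters' processing notes the authors made them with GCRMA, a method that corrects background by probe sequence, normalizes between arrays and summarises probes. No version or setting of GCRMA is given in the sources used here, and neither is the log base, which was read from the range of 0.71 to 14.7. The scanner files, detection calls, scan dates and batches were not analysed here. No columns were identical and every column belonged to a sample.

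Of the 35557 rows, 23410 were listed in the table that pairs probes with genes, 21789 with 1 symbol and 1621 with several, and 12147 were not listed and stay unnamed here. Control rows among the unlisted rows cannot be told from the file and were tested with the rest. Entrez identifiers of 21698 rows matched the gene table of assembly GRCm38.p6, which was used for names only, and 0 symbols changed. For each of 19938 genes the row with the highest mean over all arrays stood for the gene. Of 999 genes with more than 1 such row, 210 had only some rows called and 2 had called rows in both directions.

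The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend, two-sided, 14 residual degrees of freedom) on the values as deposited, with no filter, and p-values were adjusted with the Benjamini-Hochberg method over all rows. The threshold was an adjusted p of 0.05, and changes of at least 1.5-fold were counted separately. Differences are transgenic minus wildtype on the log2 scale with the standard error of the fit. GCRMA pulls dim rows towards a floor, so fold changes of dim genes are less certain than those of bright ones. On simulated data with 50 changed rows per fold among 35557, the fit recovered 44% of rows changed 1.25-fold, 98% at 1.5-fold, 98% at 2-fold and 100% at 4-fold, with 12 calls among unchanged rows.

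The 34 gene lists were fixed before the data were examined and tested with camera of limma, which asks whether a set ranks above or below all other genes, with a preset correlation of 0.01 between genes and adjustment over the lists. An estimated correlation and the fry test were alternatives. Members without a single-symbol row were left out, and counts are over measured members. In a simulation that raised the collagen list 1.5-fold, camera called that list and 0 of 33 others. Its rows were drawn independently, so it could not show false calls that arise from correlation between genes. Named genes followed a rule fixed at the same time: Pdgfc, Pdgfra, Pdgfrb, Cd34 and Vwf; the 10 largest rises and 10 largest falls among called genes with a higher-group mean above the median of the table (5.26) and all transgenic arrays on 1 side of the wildtype mean; and up to 3 called members per list by size, or the member with the smallest p. Other list members were named after their values were seen. The spread between arrays was compared as the distance of each array to its group mean, with 100000 permutations.

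Alternatives set before the data were examined were quantile normalization, centring on medians, rows above the median level, rows with 1 symbol, eBayes without trend or robust, array weights, a floor at the 20th percentile, the mean over a gene's rows, the replicate number as a block and leaving out each array in turn. Leaving out transgenic array 1 and wildtype array 9 together, and a small-group correction of the spread, were added after the data were seen. A sex covariate was planned only if the Y-linked minus Xist score ranged over more than 3 log2 units; it ranged over 0.663 and the covariate was not run. Bootstrap intervals of the closing section used 10000 resamples and cover 95%. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.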

Results

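Gene expression was measured in 16 mouse liver RNA samples, 7 from mice carrying a Pdgf-c transgene and 9 from wildtype mice of the C57BL/6 background. Pdgf-c encodes platelet-derived growth factor C, a ligand for the PDGF receptors of fibroblasts and hepatic stellate cells. Each sample was hybridised to 1 Affymetrix Mouse Gene 1.0 ST array. The labels call the samples stromal cells, while the extraction protocol describes total hepatic RNA. The row of the hepatocyte gene Alb averaged 13.5 on the log2 scale in the transgenic group and 13.6 in the wildtype group. The labels give neither the age of the mice nor whether the samples came from separate animals, so the p-values measure only the spread between these samples. The deposited table held 35557 rows, and its column medians lay between 5.20 and 5.36 on the log2 scale. Pearson's r over all rows was 0.984 to 0.991 between transgenic arrays, 0.982 to 0.991 between wildtype arrays and 0.976 to 0.987 across the groups. The first principal component held 47.3% of the variance and separated the groups without overlap. The second held 13.3%, with transgenic array 1 at 28.1 and wildtype array 9 at -23.2 as its ends. For arrays, the number of samples limits the precision.

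**Figure D1:**
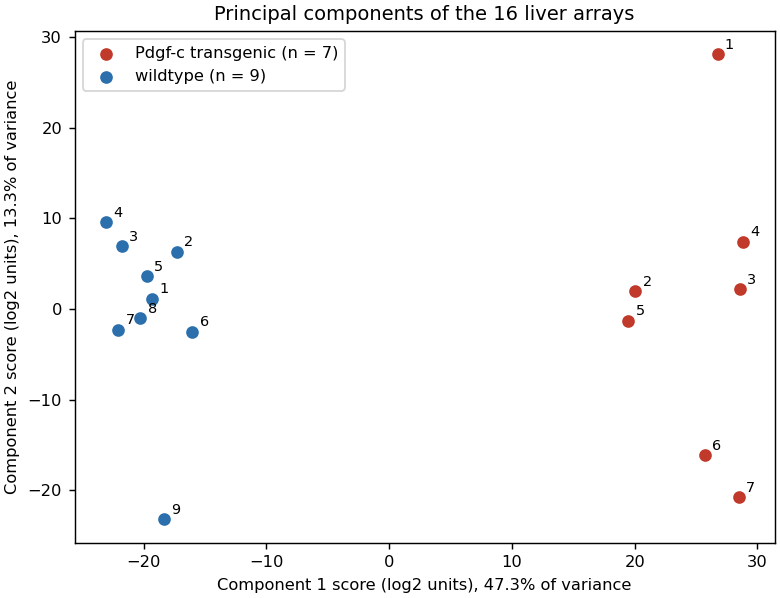
Scores of the 16 arrays on the first (47.3% of variance) and second (13.3%) principal components, in log2 units, with each point numbered by its replicate. The 7 transgenic arrays lie to the right and the 9 wildtype arrays to the left of 0 on the first component.

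The series asked whether stromal cells of the liver contribute to tumour formation in Pdgf-c transgenic mice, and the transgene and the proteins stained in its protocols were read first. The Pdgfc row was 1.36-fold higher in the transgenic group (log2 difference 0.44 ± 0.0873, SE, 7 against 9 arrays), and 6 of the 7 transgenic arrays exceeded all wildtype arrays. Pdgfra and Pdgfrb, which encode the receptor chains that bind PDGF, rose 8.98-fold (3.17 ± 0.102) and 4.05-fold (2.02 ± 0.0881). Cd34, a surface glycoprotein of vascular endothelium and some stromal cells, rose 8.83-fold (3.14 ± 0.0803), while Vwf, the endothelial von Willebrand factor, rose 1.36-fold (0.45 ± 0.0689). In each of these 4 genes all 7 transgenic arrays lay above all 9 wildtype arrays. Adjusted p-values (limma, Benjamini-Hochberg over all 35557 rows) were 0.00132 for Pdgfc, 3.79e-13 for Pdgfra, 1.98e-11 for Pdgfrb, 1.47e-14 for Cd34 and 1.15e-04 for Vwf. The labels do not state the species or part of the transgene cDNA, so the Pdgfc row may read the endogenous transcript, the transgene or both.

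The largest changes over the array came next. Mgp, an inhibitor of calcification secreted into the matrix, was 21.1-fold higher in the transgenic livers (4.40 ± 0.0766), and Itga8, the integrin alpha 8 chain, was 19.8-fold higher (4.31 ± 0.0858). Lum, a small leucine-rich proteoglycan, rose 11.8-fold (3.56 ± 0.174), Adamtsl2 10.1-fold (3.34 ± 0.0905), the LIM-domain gene Fhl2 9.47-fold (3.24 ± 0.116) and Cib3 9.03-fold (3.17 ± 0.242). Htra1, a secreted serine protease, rose 8.61-fold (3.11 ± 0.108), and Adamts5, a proteoglycan-cleaving protease, rose 8.47-fold (3.08 ± 0.112). With Pdgfra and Cd34, these were the 10 largest rises under the rule for named genes. The 10 largest falls were led by Cyp4a14, a fatty acid omega-hydroxylase, at -2.87 ± 0.412 (7.3-fold lower), followed by the macrophage genes Cd5l at -2.83 ± 0.296, Cd163 at -2.76 ± 0.121 and Clec4f at -2.70 ± 0.184. Clec4g and Dnase1l3, expressed in sinusoidal endothelium, were at -2.27 ± 0.128 and -1.88 ± 0.107, the lectin genes Clec1b and Colec10 at -2.10 ± 0.119 and -2.02 ± 0.116, and the cytochromes Cyp4a31 and Cyp2b10 at -2.11 ± 0.218 and -2.05 ± 0.252. In all 20 genes the transgenic and wildtype arrays did not overlap, and the adjusted p (limma) was at most 5.49e-05. A second Clec4g row gave -0.05 ± 0.104 (limma adjusted p = 0.808).

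Over the whole array, 3785 rows were higher and 2936 lower in the transgenic group at an adjusted p of 0.05 (limma), which is 18.9% of the 35557 rows. Of these, 1103 rose and 242 fell by at least 1.5-fold. Taking the brightest row of each of 19938 genes with a single symbol, 2422 genes were higher and 2209 lower, 754 and 173 of them by at least 1.5-fold, and 49 and 9 by at least 4-fold. The groups did not overlap in 1564 higher rows and 848 lower rows, where chance gives 0.0175% of rows in both directions together. The share of called rows that were higher was 56.3% as deposited, 48.3% after quantile normalization (3583 higher, 3829 lower) and 38.0% with each array centred on its median (2873 higher, 4688 lower). The balance of small changes in the 2 directions therefore depended on the scaling, and the median row shifted by -0.03 as deposited and by -0.08 after centring.

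**Figure D2:**
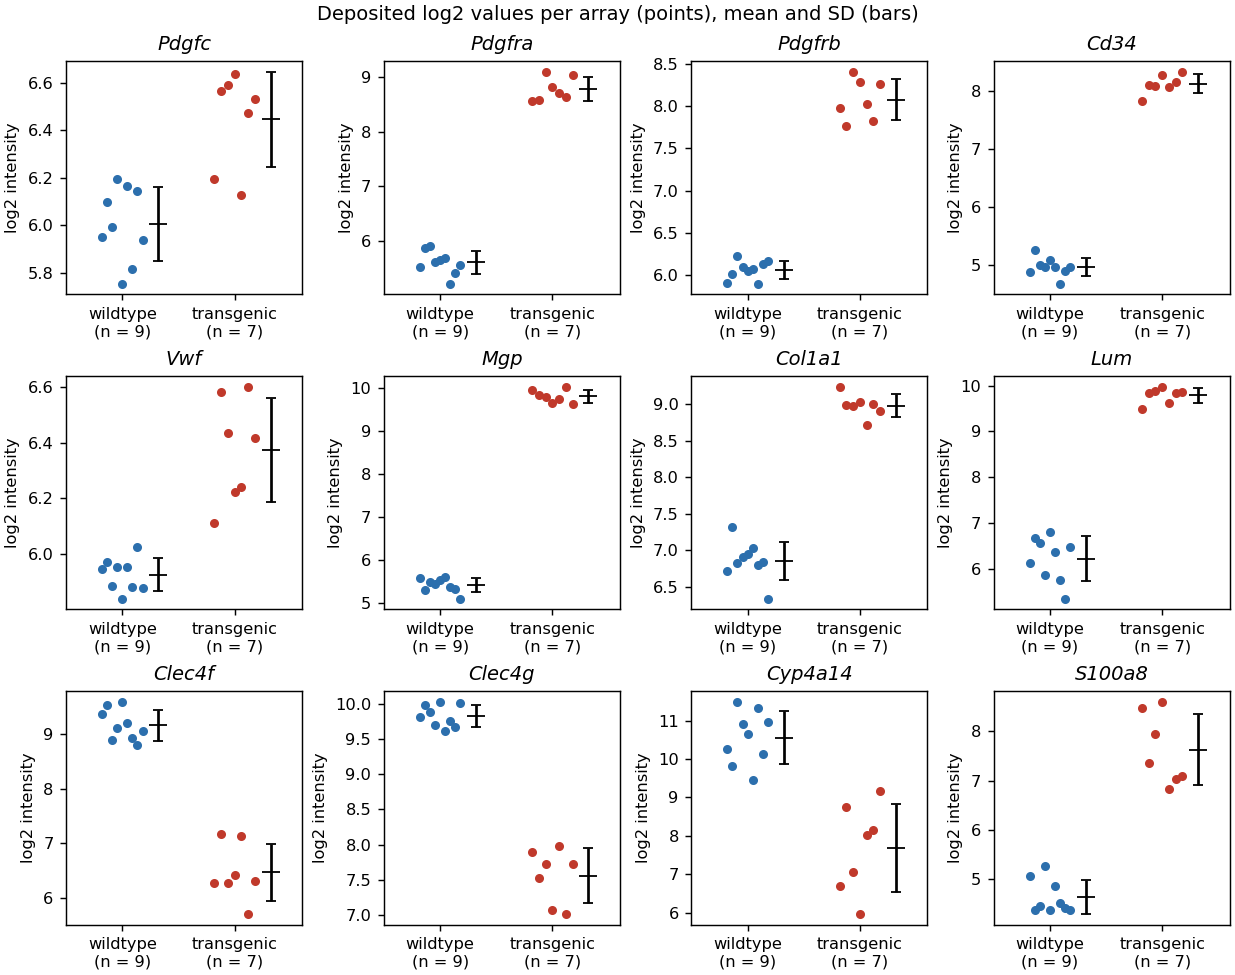
Deposited log2 values of 12 genes in each of the 9 wildtype and 7 transgenic arrays (points), with the group mean and SD (bars). The groups do not overlap in any panel except Pdgfc, where 6 of the 7 transgenic arrays lie above all wildtype arrays, and each panel has its own axis range.

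Lists of stromal genes, fixed like all 34 lists before the data were examined, rose as sets. Of 18 fibrillar and basement membrane collagens, 12 rose and none fell, led by Col6a3 at 5.96-fold (2.58 ± 0.0639), Col1a1 at 4.34-fold (2.12 ± 0.105) and Col3a1 at 3.83-fold (1.94 ± 0.102); adjusted over the list alone, 14 were higher and 1 lower, and with arrays centred on their medians 1 was lower over all rows. Among 28 non-collagen matrix genes 20 rose and 1 fell (20 and 2 adjusted over the list alone, and 2 lower over all rows without transgenic array 1 or wildtype array 9). Beside Mgp and Lum, the proteoglycan gene Ogn rose 6.94-fold (2.79 ± 0.144), whereas Postn, which encodes the matricellular protein periostin, was the gene that fell (-1.23 ± 0.106). Fibronectin, Fn1, differed by -0.02 ± 0.052 (limma adjusted p = 0.852). Of 29 matrix remodelling genes, 18 rose and 1, Mmp19, fell (18 and 1 adjusted over the list alone), with the lysyl oxidase Loxl1 at 6.01-fold (2.59 ± 0.0814) and the gelatinase Mmp2 at 4.98-fold (2.32 ± 0.0796). Timp1, an inhibitor of matrix metalloproteinases, rose 1.27-fold and Timp2 3.59-fold.

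Hepatic stellate cell and myofibroblast markers rose in 14 of 20 genes, and 1 gene, Rgs5, fell (-1.17 ± 0.129). Adjusted over the list alone, 15 were higher and 1 lower. The intermediate filament gene Vim rose 4.36-fold (2.12 ± 0.0951) and the stellate cell globin Cygb 3.5-fold (1.81 ± 0.106). Acta2, the smooth muscle actin of myofibroblasts, rose 1.49-fold (0.58 ± 0.133), and Gfap differed by -0.05 ± 0.0952 (limma adjusted p = 0.799). Of 9 PDGF ligand, receptor and processing genes, 8 rose and none fell (8 and 1 adjusted over the list alone, and 1 lower over all rows after quantile normalization or centring, or without transgenic array 7 or wildtype array 2 or 3), including the ligand genes Pdgfd at 2.34-fold (1.23 ± 0.127) and Pdgfa at 1.8-fold (0.84 ± 0.0734). In the TGF-beta pathway 11 of 19 genes rose and 2, Bmp2 and Bmp6, fell (11 and 2 adjusted over the list alone, and 1 lower over all rows without transgenic array 4 or 6). Ccn2, the connective tissue growth factor, rose 3.24-fold (1.70 ± 0.16), Pmepa1 2.9-fold (1.54 ± 0.0707) and Tgfbi 2.87-fold (1.52 ± 0.0815), while Tgfb1 itself rose 1.2-fold (0.26 ± 0.0716). As sets against all other genes (limma camera, preset correlation of 0.01, adjusted over 34 lists), the adjusted p was 1.27e-21 for non-collagen matrix, 6.49e-15 for remodelling, 3.34e-14 for collagens, 9.30e-14 for stellate cell markers, 4.78e-10 for the PDGF genes and 2.25e-07 for the TGF-beta genes. These 6 sets kept their calls with an estimated correlation, with adjusted p-values from 0.000275 to 0.0064.

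Endothelial genes moved in both directions. Of 17 genes of liver sinusoidal endothelium, 11 fell and 2 rose (12 and 2 adjusted over the list alone), with coagulation factor VIII, F8, 2.45-fold lower (-1.29 ± 0.104) beside Clec4g and Dnase1l3; the scavenger receptor gene Stab2 stood at -0.56 ± 0.085 and the receptor gene Gpr182 at -1.23 ± 0.0828. The 2 that rose were Rspo3 (0.52 ± 0.0791) and Gata4 (0.23 ± 0.0517), and Lyve1 differed by -0.17 ± 0.126 (limma adjusted p = 0.394). The set as a whole was lower (camera adjusted p = 1.59e-08) and kept its call with an estimated correlation (adjusted p = 0.0188). In the broader vascular and angiogenesis list 11 of 27 genes rose and 3 fell (12 and 3 adjusted over the list alone). Beside Cd34, the sialoglycoprotein gene Emcn rose 2.34-fold (1.23 ± 0.117) and Eng, a TGF-beta co-receptor, 1.97-fold (0.98 ± 0.058), whereas Kdr, the main VEGF receptor, was 2.02-fold lower (-1.01 ± 0.0976). The set was higher at a camera adjusted p of 0.000129, with an adjusted p = 0.0669 with an estimated correlation. Pecam1 rose 1.27-fold (0.35 ± 0.0929), and Cdh5, the vascular cadherin, differed by -0.06 ± 0.0665 (limma adjusted p = 0.569).

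Macrophage genes moved in both directions. Of 24 genes of Kupffer cells and macrophages, 14 rose and 6 fell (15 and 6 adjusted over the list alone). The 6 that fell, Cd5l, Cd163, Clec4f, Timd4, Vsig4 and Marco, are markers of resident Kupffer cells and ranged from -2.83 to -0.67. Among those that rose were Ms4a7 at 4.79-fold (2.26 ± 0.128), the fractalkine receptor Cx3cr1 at 4.59-fold (2.20 ± 0.106), the monocyte chemokine receptor Ccr2 at 4.01-fold and lysozyme, Lyz2, at 3.32-fold (1.73 ± 0.17). The pan-macrophage gene Adgre1 differed by 0.26 ± 0.156 (limma adjusted p = 0.284). The set was higher at a camera adjusted p of 8.02e-05, with an adjusted p = 0.271 with an estimated correlation; its median was 0.53 and its mean 0.20, and on the brighter rows alone the mean was -0.02 (camera adjusted p = 0.0923).

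Genes of other immune cells were higher in part. Lymphocyte genes rose in 10 of 22 cases and fell in none (11 and 0 adjusted over the list alone), with Cd52 at 3.32-fold (1.73 ± 0.124), the leukocyte antigen Ptprc at 1.96-fold (0.97 ± 0.0905) and Nkg7 at 1.78-fold (0.84 ± 0.115); Cd4 differed by 0.02 ± 0.0995 (limma adjusted p = 0.927). The set was higher (camera adjusted p = 1.46e-05; adjusted p = 0.0296 with an estimated correlation). Of 12 neutrophil genes 8 rose and none fell (8 and 0 adjusted over the list alone). The calgranulin genes S100a8 and S100a9 rose 7.93-fold (2.99 ± 0.245) and 3.39-fold (1.76 ± 0.198), and the granule gene Ngp was higher (limma adjusted p = 2.89e-05) with a wildtype mean of 3.09, below the 20th percentile of the table (3.45), so no fold is given. The camera adjusted p was 3.04e-07 for this set, with an adjusted p = 0.0775 with an estimated correlation. Of 32 chemokine and cytokine genes, 10 rose and 2 fell (13 and 3 adjusted over the list alone), with Ccl3 at 2.23-fold (1.16 ± 0.131) and Cxcl16 at a log2 difference of 1.00 ± 0.114 above wildtype and the B-cell chemokine Cxcl13 2.57-fold below (-1.36 ± 0.202). Tnf differed by 0.17 ± 0.107, Il6 by -0.21 ± 0.113 and Il1b by 0.25 ± 0.104, with limma adjusted p-values of 0.307, 0.225 and 0.113. The camera adjusted p was 0.00157 here, with an adjusted p = 0.0789 with an estimated correlation. Interferon response genes rose in 12 of 17 cases (14 adjusted over the list alone) and none fell, led by Ifi27l2a at 2.58-fold (1.37 ± 0.193), Ifit2 at 2.33-fold (1.22 ± 0.163) and Ifit3 at 2.02-fold (1.01 ± 0.122). That set had a camera adjusted p of 2.42e-08 and an adjusted p = 0.0808 with an estimated correlation.

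Cell cycle genes rose in 18 of 33 cases, and Ccne1 fell (24 higher and 2 lower adjusted over the list alone). None was lower without transgenic array 1, 3 or 7 or wildtype array 1, 7 or 9. Top2a, the topoisomerase of dividing cells, rose 2.03-fold (1.02 ± 0.144), the cyclin gene Ccnd2 by 1.00 ± 0.0806 on the log2 scale, the replication helicase gene Mcm6 1.84-fold (0.88 ± 0.0864) and the proliferation marker Mki67 1.43-fold (0.52 ± 0.116). A second Top2a row gave -0.07 ± 0.0896 (limma adjusted p = 0.678). Its mean over all arrays was 1.92, below the 20th percentile of the table (3.45), so it bears little on the change of Top2a. Among 21 liver tumour and fetal liver markers 9 rose and none fell (10 and 0 adjusted over the list alone): Tff3, a secreted trefoil peptide, rose 7.03-fold (2.81 ± 0.235), the desaturase gene Scd2 2.39-fold (1.26 ± 0.105) and Ly6d 1.87-fold (0.90 ± 0.216). The oncofetal genes Afp and Gpc3 differed by 0.09 ± 0.0956 and 0.16 ± 0.124, and Myc by 0.82 ± 0.301 (limma adjusted p-values 0.595, 0.422 and 0.0667). Cholangiocyte and progenitor markers rose in 6 of 16 cases and 1, Prom1, fell (7 and 1 adjusted over the list alone, and 0 lower over all rows without transgenic array 1, 4, 6 or 7 or wildtype array 1, 2 or 7), with Cd24a at 2.61-fold (1.38 ± 0.144), Krt23 at 1.87-fold (0.91 ± 0.21) and Krt18 at 1.59-fold (0.67 ± 0.0875); Krt19 and Sox9, which mark bile duct cells, differed by 0.10 ± 0.0693 and -0.07 ± 0.0847 (limma adjusted p-values 0.362 and 0.622). Camera adjusted p-values were 1.53e-09 for cell cycle, 3.09e-05 for tumour and fetal markers and 0.0028 for cholangiocyte markers, and the adjusted p was 0.0496, 0.00295 and 0.0296 with an estimated correlation. Of 19 Wnt targets and pericentral genes, 4 rose and 1, Cyp1a2, fell (4 and 1 adjusted over the list alone), with the amino acid transporter gene Slc1a4 at 1.61-fold (0.68 ± 0.106) and Gulo, an enzyme of ascorbate synthesis, at 1.34-fold (0.42 ± 0.0417). Axin2 and Lgr5 differed by 0.22 ± 0.108 and 0.30 ± 0.136 (limma adjusted p-values 0.191 and 0.151). The Wnt set had a camera adjusted p of 0.036, with an adjusted p = 0.284 with an estimated correlation, and lost its call without transgenic array 4 (adjusted p = 0.0733), transgenic array 5 (0.0618) or wildtype array 2 (0.0583), on rows above the median level (0.166) and with a floor at the 20th percentile (0.058).

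Genes of fatty acid oxidation and of drug metabolism were lower in the transgenic livers. Fatty acid oxidation genes fell in 14 of 19 cases and 1 rose (14 and 1 adjusted over the list alone): beside Cyp4a14, Cyp4a10 was 3.53-fold lower (-1.82 ± 0.164), the acyl-CoA thioesterase gene Acot1 3.2-fold lower (-1.68 ± 0.185) and the peroxisomal gene Ehhadh 1.58-fold lower (-0.66 ± 0.105). Pdk4, a kinase that inhibits pyruvate dehydrogenase, was the gene that rose (0.95 ± 0.168), and Cpt1a differed by -0.02 ± 0.0523 (limma adjusted p = 0.871). Cytochrome P450 and drug metabolism genes fell in 16 of 21 cases and 1, Gstm3, rose (18 and 1 adjusted over the list alone). Cyp2c37 was 2.12-fold lower (-1.08 ± 0.216) and Cyp2c39 1.97-fold lower (-0.98 ± 0.1), while Cyp3a11 differed by -0.12 ± 0.0493 (limma adjusted p = 0.0922). Both sets were lower (camera adjusted p = 1.06e-09 and 1.69e-09) and kept their calls with an estimated correlation (adjusted p = 0.0496 and 0.0357).

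Changes of hepatocyte identity genes were small in the brightest rows and larger in the dimmest. Rows with wildtype means from 13.35 (Ahsg) to 13.66 (Apoa2) differed by -0.11 (Ttr) to 0.07 (Apoa1). The dimmest rows, from F9 (wildtype mean 9.65) to G6pc (11.53), differed by -0.20 (Cebpa) to -0.54 (G6pc, not called). Whether the brightest rows report changes in full was not tested, so these values do not measure hepatocyte content. Of 24 genes, 11 fell and 1, Apoa1, rose, though not after centring or without transgenic array 1, 3 or 4 or wildtype array 1, 4 or 7 (13 and 1 adjusted over the list alone), with Otc of the urea cycle at -0.51 ± 0.0487, coagulation factor F9 at -0.33 ± 0.0678 and Arg1 at -0.29 ± 0.0541; Alb differed by -0.02 ± 0.0316 (limma adjusted p = 0.726). The set median was -0.12, with a camera adjusted p of 0.000987 and an adjusted p = 0.0679 with an estimated correlation. Of 23 bile acid genes, 11 fell and none rose (12 lower and 1 higher adjusted over the list alone, and 1 higher over all rows after quantile normalization or without transgenic array 1 or 3 or wildtype array 1, 3 or 7), with the bile salt export pump gene Abcb11 at -0.44 ± 0.111 and the peroxisomal oxidase gene Acox2 at -0.37 ± 0.084; Cyp7a1, the rate-limiting enzyme of bile acid synthesis, differed by 0.26 ± 0.226 (limma adjusted p = 0.489). Their camera adjusted p was 0.00233, with an adjusted p = 0.236 with an estimated correlation. Without transgenic array 1 and wildtype array 9, a choice made after the principal components were seen, 9 bile acid genes were lower and 3 higher. Acute phase genes fell in 11 of 24 cases and 1, Steap4, rose (13 and 2 adjusted over the list alone, and 2 higher over all rows without wildtype array 1), with the lipopolysaccharide-binding protein gene Lbp at -0.66 ± 0.121 and Hamp, the iron hormone hepcidin, at -0.54 ± 0.102; Saa1 and Saa2 differed by 0.26 ± 0.305 and 0.67 ± 0.279 (limma adjusted p-values 0.632 and 0.109). That set had a camera adjusted p of 0.0108 and an adjusted p = 0.341 with an estimated correlation. Genes of fatty acid and triglyceride synthesis rose in 10 of 24 cases and fell in 3 (11 and 4 adjusted over the list alone), with the elongase gene Elovl6 at 2.09-fold (1.07 ± 0.141) and Acaca, which makes malonyl-CoA, at 1.83-fold (0.87 ± 0.0837). Fasn, the fatty acid synthase, rose 1.44-fold (0.53 ± 0.105), and Me1 and Srebf1 were lower (-0.41 ± 0.111 and -0.28 ± 0.0927). The set was higher at a camera adjusted p of 0.00435, with an adjusted p = 0.144 with an estimated correlation. Of 17 cholesterol synthesis genes 2 were lower, Tm7sf2 (-0.42 ± 0.0692) and Stard4 (-0.32 ± 0.108), and 1 adjusted over the list alone (limma camera adjusted p = 0.259). The number lower was 4 without wildtype array 1, and 1 without transgenic array 1, 2, 3 or 4 or wildtype array 3, 5, 6, 7, 8 or 9. Of 14 oxidative stress genes 5 were lower and 2 higher, the same counts adjusted over the list alone, with the carbonyl reductase gene Cbr3 at 1.87-fold (0.90 ± 0.111) and the glutathione synthesis gene Gclc at -0.44 ± 0.0984 (limma camera adjusted p = 0.33).

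Lists that track handling, time of day, sex, blood, other tissues and housekeeping were not called as sets by camera with all arrays. Of 18 immediate early and heat shock genes 3 were higher and 1 lower, also adjusted over the list alone: Jun (0.50 ± 0.118), Ier3 (0.46 ± 0.0983) and Atf3 (0.37 ± 0.114) rose and Zfp36 fell (-0.31 ± 0.0961). Here 2 were lower without transgenic array 2, and 0 without transgenic array 3, 4 or 5 or wildtype array 1, 2 or 3. Of 15 clock genes 4 fell and 1 rose (5 and 1 adjusted over the list alone), with the clock repressor gene Ciart at -0.68 ± 0.0939 and Nfil3 at -0.48 ± 0.128; 2 fell without transgenic array 3 or 6, and none rose without transgenic array 3, 4, 5 or 7 or wildtype array 1, 2, 3, 4, 5 or 7. None of the 4 measured Y-linked and Xist genes was called in either analysis (Kdm5d had the smallest p, at 0.26 ± 0.131, limma adjusted p = 0.198). Male-biased liver genes were higher in 1 of 14 cases, C6 (0.76 ± 0.11), and lower in 4, including Elovl3 at -0.70 ± 0.159 (1 and 5 adjusted over the list alone). Without wildtype array 3, 7 of them were lower and the set was called (camera adjusted p = 0.0203). Of 13 female-biased genes 3 fell, with Acot3 at -1.71 ± 0.238, and 2 rose, Ntrk2 (1.18 ± 0.182) and Fmo2 (0.57 ± 0.171); adjusted over the list alone, 4 were lower and 2 higher, while 1 was lower without transgenic array 1, 4 or 6 or wildtype array 7, and 1 higher without transgenic array 2, 3 or 6. Alas2 (-0.45 ± 0.0918) and Klf1 (-0.30 ± 0.0899) fell among 4 erythroid genes, Cela1 (-0.50 ± 0.0659) and Lgals4 (-0.40 ± 0.124) fell among 15 genes of neighbouring tissues, and the mesothelial list of 8 held 1 gene that rose, Wt1 (0.55 ± 0.0966), each count unaltered when adjusted over the list alone. The erythroid list had 1 lower without transgenic array 2 or 4, and the neighbouring tissue list 1 without transgenic array 2, 3, 5 or 6 or wildtype array 6, 7 or 8. Of 11 housekeeping genes 3 rose, led by Ywhaz at 1.32-fold (0.40 ± 0.0413) and Actb at 1.26-fold (0.34 ± 0.0449), and Sdha fell (-0.28 ± 0.0666), with 3 lower after quantile normalization and 2 after centring or without transgenic array 5 or wildtype array 1 or 6; adjusted over the list alone, 5 were higher and 2 lower. Camera adjusted p-values for these 9 sets lay between 0.12 and 0.779. The median and mean differed in sign for the immediate early (-0.01 and 0.00435), mesothelial (-0.04 and 0.03) and housekeeping lists (-0.03 and 0.07), whose camera direction followed the mean.

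**Figure D3:**
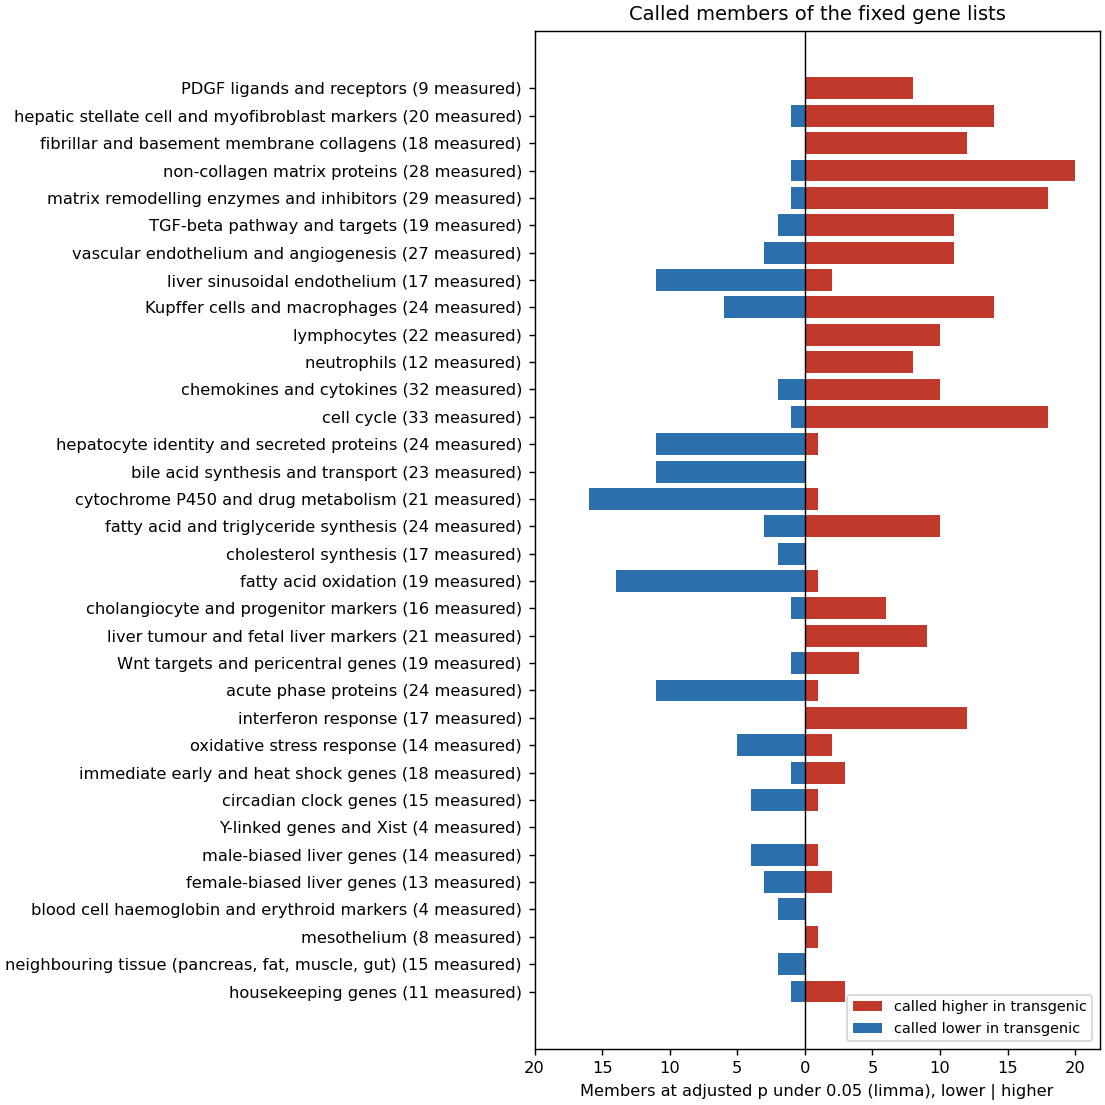
Number of measured members of each of the 34 gene lists called lower (left of 0) and higher (right of 0) in the transgenic arrays at an adjusted p of 0.05 (limma). Collagen, matrix and remodelling lists have 12, 20 and 18 members to the right, and the sinusoidal, cytochrome P450 and fatty acid oxidation lists have 11, 16 and 14 to the left.

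Over the 34 lists, camera called 17 sets higher and 6 lower, and 10 and 3 with an estimated correlation. The fry test, which asks whether the genes of a set move on balance one way and does not compare them with other genes, called 18 higher and 9 lower, adding the clock, erythroid and neighbouring tissue sets as lower and the housekeeping set as higher. Without transgenic array 1 and wildtype array 9, 9 fatty acid synthesis genes were higher and 1 lower, 6 Wnt and pericentral genes higher and 1 lower, and 20 cell cycle genes higher and 0 lower. Among the named genes, 10 had calls that were lost when single arrays were left out in turn: Stard4 and Per3 (0.31 ± 0.101) in 10 of 16 cases each, Cyp7b1 (-0.49 ± 0.157) in 9, Orm2 (-0.66 ± 0.216) and Lgals4 in 7 each, Atf3 in 5, Fmo2 in 3, Ccnd1 (0.50 ± 0.151) and Klf1 in 2 each and Aox1 (-0.39 ± 0.116) in 1. Their largest adjusted p (limma) in those fits lay between 0.054 for Aox1 and 0.0997 for Stard4.

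Transgenic livers were also compared with wildtype livers for how far single arrays lay from their group mean. The distance averaged 0.181 ± 0.0383 (SD, n = 7) in the transgenic group and 0.175 ± 0.0263 (SD, n = 9) in the wildtype group, over 17778 rows above the median level. The difference of 0.00687 did not exceed the spread between arrays (permutation test, two-sided, 100000 resamples, p = 0.658). Transgenic array 1 (0.256) and wildtype array 9 (0.241) lay farthest from their group means. Without transgenic array 1 the difference was -0.0101 (permutation p = 0.501), and over all rows it was -0.00803 (permutation p = 0.665). Distances to the mean of a smaller group come out shorter, and with the small-group correction, added later, the difference was 0.0108 (permutation p = 0.539).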

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

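The comparison within groups that picked out the values below was fixed before the data were examined, and no test here was chosen after a result was seen. A value is given where the highest or lowest array of a group stood apart by more than Dixon's critical value for the gap over the range of the group. Of 210 groups of values examined, 14 met this, and chance gives 10.5. In the wildtype group, array 9 had 4 of them: a score of -23.2 on the second principal component (the nearest array was at -2.49), and high values of Dnase1l3 (8.18), Ccnd2 (7.52) and Lgals4 (7.70). Wildtype array 3 had the highest Cyp2b10 (8.66, next 6.94), Atf3 (6.17) and Fmo2 (8.18) of its group, and wildtype array 8 the lowest Nkg7 (4.73, next 5.16). Among transgenic arrays, array 1 had the lowest Tgfbi (9.01) and Gclc (9.76), array 4 the lowest Acox2 (9.15) and array 5 the lowest Jun (7.07, next 7.63). Transgenic array 6 had the highest Scd2 (7.09, next 6.66) and Ntrk2 (6.42, next 5.21), the latter a neurotrophin receptor gene. Without wildtype array 9, 3957 rows were higher and 2984 lower in the transgenic group, against 3785 and 2936 with it.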

How the results depend on the processing

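Settings added after the data were seen are the joint omission of transgenic array 1 and wildtype array 9 and the small-group correction of the spread; all others were planned. Across normalizations, filters, moderation, array weights and floor, the counts of rows and genes stayed within 1.5 times the reported ones, except that centring each array on its median gave 4688 lower rows and 3350 lower genes, which follows from lowering the transgenic arrays, whose medians were higher on average. Of the 4631 called genes, 4069 were called in the same direction after centring, 4202 after quantile normalization and 4174 without transgenic array 1 and wildtype array 9, where 4176 rows were higher and 3101 lower. Leaving out each array in turn gave 3380 to 3957 higher and 2513 to 2984 lower rows, 2172 to 2532 higher and 1913 to 2224 lower genes. Camera with an estimated correlation called 10 lists higher and 3 lower in place of 17 and 6. Only the correlation setting differed between these runs, so the lost calls rested on the preset value of 0.01. The difference in spread was -0.00803 over all rows, and -0.0101 to 0.0179 with single arrays left out; the cause was not tested. Equal replicate numbers did not pair the arrays: their deviations correlated at -0.0366 to 0.116, 1 of 7 pairs exceeded 0.1 and 0 of 7 correlated best with its own number. The fit with a replicate block called 3487 rows higher and 2237 lower, and with it the members called lower numbered 5 in the cholesterol list (2 without the block), 2 in the male-biased (4), 1 in the female-biased (3), 2 in the oxidative stress (5), 1 in the fatty acid synthesis (3) and 4 in the immediate early list (1). Under the block Gclc, Lgals4, Aox1, Atf3 and Cyp7b1 lost their calls (limma adjusted p = 0.0683, 0.0576, 0.102, 0.115 and 0.115), and Kdm5d was called higher (0.0431). No cholangiocyte marker was lower with the block, with array weights or on rows above the median level. On those rows 9 macrophage, 6 lymphocyte and 3 neutrophil genes were higher, in place of 14, 10 and 8. The mean of the immediate early list was -0.0464 under that replicate block. The mesothelial mean was -0.0142 without transgenic array 1 and wildtype array 9 and ranged from -0.00367 to 0.0498 with single arrays left out, and the mean of the Y-linked and Xist list from -0.00847 to 0.093; none of these lists was called and the cause was not tested. Under quantile normalization Cyp7b1, Stard4, Atf3 and Per3 lost their calls (limma adjusted p = 0.0552, 0.0506, 0.0776 and 0.0736), and Atf3 and Per3 also after centring (0.0527 and 0.0975). With the floor Cyp7b1, Stard4, Orm2 and Per3 lost theirs (0.0584, 0.0664, 0.0622 and 0.0507), Stard4 without trend (0.057) and Orm2 with array weights (0.0574). Without transgenic array 1 and wildtype array 9 this held for Stard4, Ccnd1, Orm2, Aox1 and Atf3 (0.134, 0.0685, 0.0726, 0.0731 and 0.0613). The male-biased list was called lower without wildtype array 3 (camera adjusted p = 0.0203). No detection calls were used, so how far dim rows rise above background is not known.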

Other observations

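Gene groups in this part were drawn up after the largest changes and the list medians had been seen. Tests chosen after the result was seen are those of dilution for all 3 patterns below and of residual blood; those of fewer endothelial cells, feeding state, the Pdgfc and collagen relation and the random splits were written before. Of 11 genes, chiefly of MHC class II antigen presentation, 10 rose. The dendritic cell genes among them were Flt3, which rose (0.48 ± 0.103), and Cd209a, which was not called (0.15 ± 0.0609, limma adjusted p = 0.11). H2-Aa was 4.77-fold higher in the transgenic livers (2.25 ± 0.109, SE, 7 against 9 arrays), H2-Eb1 4.6-fold higher (2.20 ± 0.122) and H2-Ab1 3.98-fold higher (1.99 ± 0.113), while Ciita, the activator of these genes, rose 1.34-fold (0.42 ± 0.0696). Of 13 cytoskeletal, actin-binding, annexin and S100 genes, 12 rose, with the actin-severing gene Gsn at 7.01-fold (2.81 ± 0.0871), the thymosin gene Tmsb10 at 3.95-fold (1.98 ± 0.0816) and Anxa2 at 3.66-fold (1.87 ± 0.117). Apart from Flt3 (0.00259) and Cd209a, limma adjusted p-values of the genes named so far were at most 2.47e-04.

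Genes that mark stellate cells of normal liver moved apart. Hgf, the hepatocyte growth factor, rose 3.05-fold (1.61 ± 0.115), Lrat, which makes retinyl esters, 2.3-fold (1.20 ± 0.182), and Reln 2.04-fold (1.03 ± 0.129). Colec10 (-2.02 ± 0.116), Angptl6 (-1.39 ± 0.062), Rgs5 (-1.17 ± 0.129) and Ecm1 (-0.54 ± 0.0863) fell. Of 9 such genes 4 rose, 4 fell and Ngfr was not called. Of 28 non-collagen matrix genes 20 rose, 7 were not called and Postn fell (-1.23 ± 0.106). Igfbp1, an insulin-repressed secreted protein of hepatocytes, rose 2.7-fold (1.43 ± 0.243), and Creb3l3, a hepatocyte transcription factor, was 1.71-fold lower (-0.78 ± 0.0463).

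On the planned list of 24 Kupffer cell and macrophage genes 14 rose and 6 fell. The 6 that fell are known markers of resident Kupffer cells and were grouped as such after their values had been seen, so their shared direction and median (-2.24) follow from the choice. Markers of infiltrating macrophages, picked from the same list after their values had been seen, had a median of 1.04. A larger stromal share that dilutes all resident cells would lower Kupffer cell and hepatocyte genes alike. For these 6 genes the median relative to hepatocyte genes was -2.12 (95% interval -2.36 to -1.78 over arrays and -2.85 to -0.682 over arrays and genes). The second interval was all but bound to lie below 0, since the genes were chosen for their falls. Their single values ran from -2.83 to -0.67, against a lowest hepatocyte value of -0.54. This argues against equal dilution for these genes only, not for Kupffer cell markers chosen otherwise. All 6 were dimmer in wildtype livers (Clec4f the brightest, at 9.17) than the dimmest hepatocyte gene (F9, 9.65), which limits the comparison. Blood left in the tissue would raise erythroid genes with the macrophage genes, whereas of 7 erythroid genes 0 were called higher and 2 lower (median -0.17, interval over arrays -0.246 to -0.0298). Relative to the macrophage genes, whose height depends in part on their choice, this median lay at -1.21 (-1.41 to -0.988, and -2.36 to -0.801). A candidate explanation, as a hypothesis, is that resident Kupffer cells were replaced by monocyte-derived macrophages in the transgenic livers. No test here tells this from a loss of marker expression without loss of cells, which stays open.

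Of 12 sinusoidal endothelial markers 8 fell and 1, Gata4, rose (median -0.78), while 5 of 15 genes shared by endothelial cells rose and 4 fell (median -0.06). For dilution, the sinusoidal median lay at -0.67 relative to hepatocyte genes (-0.816 to -0.556 over arrays, -1.19 to -0.0858 over arrays and genes). For fewer endothelial cells, the shared endothelial genes lay at 0.72 relative to the sinusoidal ones (0.589 to 0.809, and 0.0897 to 1.34). Each interval excludes 0, but the sinusoidal and shared endothelial lists were drawn up after the planned list medians had been seen. The intervals therefore weigh only weakly against equal dilution or equal loss of all endothelial cells as the whole cause. The planned list of 17 sinusoidal genes had a median of -0.69, with 11 lower and 2 higher, and the planned hepatocyte list one of -0.12. Hepatocyte genes were mostly brighter than these markers, which limits the comparison for dilution. No hepatocyte gene lay below -0.54, against a sinusoidal median of -0.78. The dimmest of them, F9, had a wildtype mean of 9.65, however, above every sinusoidal marker except Clec4g (9.83). How far dilution would lower rows as dim as the other markers is therefore not known. The bounds fixed for a decision (-0.3 and 0.3) are passed by the intervals over arrays, which were added after the others had been seen, but not by those over arrays and genes, the ones first set. Among the shared endothelial genes Eng (0.98 ± 0.058) and Ramp2 (0.58 ± 0.065) rose, while Kdr (-1.01 ± 0.0976) and Ptprb (-0.96 ± 0.0823) fell with the sinusoidal markers. A part played by either explanation therefore stays open, and a change of sinusoidal endothelial identity may be a further one, which was not tested apart from them.

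PPAR-alpha targets, genes of fat burning induced by fasting, fell in 15 of 20 cases (median -0.47), and Pdk4, a member, rose. Their median lay at -0.36 relative to hepatocyte genes (-0.564 to -0.184 over arrays, -0.73 to -0.124 over arrays and genes). The bound of -0.3 lies inside both intervals. Dilution alone would put this value near 0 only if bright and dim genes fell alike. The dimmest hepatocyte genes, F9 (-0.33), Hnf4a (-0.25), Otc (-0.51), Cebpa (-0.20) and G6pc (-0.54), all lay below the list median of -0.12. How far dilution would lower the dimmer targets is therefore not known. Fasting-induced genes outside this group had a median of 0.05, which is 0.52 above the PPAR-alpha targets (0.215 to 0.704, and 0.105 to 1.00), again with the bound of 0.3 inside. Those 11 genes moved both ways, with 2 called higher and 1 lower, from G6pc at -0.54 to Igfbp1 at 1.43. Here too each interval excludes 0, for lists of targets and fasting genes drawn up after the planned list medians had been seen. Bright reference genes limit the comparison for dilution, and a list that moved both ways limits the one for feeding state. Neither dilution nor a difference in feeding state could be decided with these bounds, and the labels give no feeding state. Lower PPAR-alpha activity in the transgenic livers may account for the pattern and was not tested apart from them.

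Across the 7 transgenic arrays, the Pdgfc value and the mean of 18 collagens gave Spearman's rho of -0.18 (exact permutation p = 0.713) and Pearson's r of -0.42 (exact permutation p = 0.364), both with an adjusted p of 0.713 over the 2 relations, and r was 0.22 without the 2 arrays farthest from the median of Pdgfc. With 7 arrays, neither a relation nor its absence could be shown. Of 100 splits of the 16 arrays into 7 and 9, the real one included, 1 gave as many called rows as the real one (6721, highest other 1) and 1 as many at 1.5-fold (1345, highest other 1). A random grouping of these arrays thus rarely gave such counts, as far as 100 splits can show. In the other splits both parts mixed transgenic and wildtype arrays, so genotype differences added to the spread within parts and lowered the counts. These counts therefore do not show how many rows would be called without a genotype difference. The labels do not say whether the samples came from separate animals. As many lists as the real 23 were called by camera in 3 of 100 splits, the highest other also calling 23. The other 2 of these splits put 5 and 1 of the 7 transgenic arrays in the smaller part. The share lies under 0.05, yet camera with a preset correlation called many lists in splits that called at most 1 row. Splits that shared out the genotypes unevenly called most, whereas those with 3 transgenic arrays in the smaller part called from 0 to 10 lists. The list calls of other splits thus in part followed the genotype difference and do not count false calls of camera. Up to 10 lists were still called where the genotypes were shared out almost evenly.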
